A study of Mus musculus with 6 samples.

How the data were processed

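Gene expression was measured in whole mouse kidneys at embryonic day 12.5 on 6 single-colour Affymetrix oligonucleotide arrays, 3 of normal kidneys and 3 of kidneys in which a loxP-flanked beta-catenin gene (Ctnnb1) meets Cre recombinase driven by the Hoxb7 promoter, which is active in the ureteric bud. Per the labels, the loxP sites lie around exons 2 to 6, dissected kidneys were shared out at random among 3 vials, and 1 µg of total RNA per sample went through a single amplification cycle with biotin labelling. Groups were taken from the sample titles. For the 3 knockout samples the title and source name say knockout, but the description field repeats the wording used for normal kidneys, and the array values do not settle this conflict. The labels call the samples biological replicates but do not give the number of animals per vial, so p-values measure the spread between these samples, part of which may be technical.

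The deposited values are one linear signal intensity per probe set, made by the authors with MAS5 per the submitters' processing notes. The version of MAS5, its detection calls and its other parameters are not given in the sources used here. On each of the 6 arrays the deposited intensity had a mean of 150.0 after trimming at the 2nd and 98th percentile, which is how MAS5 global scaling leaves an array. The medians ran from 24.9 to 32.1 and spanned 0.37 on the log2 scale, less than the limit of 0.5 set before the data were examined, so the values were used with no further scaling. Because MAS5 subtracts mismatch signal, values near the floor scatter widely on a log scale, and 15 values of 0 were set to 1.7, the 10th percentile of positive values, before log2.

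Of 45101 probe sets, 64 Affymetrix controls were left out of the tests. Probe sets were kept where the mean log2 signal over all arrays lay above the 40th percentile, a signal of 14.7, which left 27022. Symbols came from the platform annotation and were updated through gene identifiers in the reference gene table. Among the 45037 remaining probe sets, 34945 had 1 symbol, 932 had several and 9160 had none here. No gene was named from a probe set with several symbols. A gene was represented by its brightest kept probe set, by mean log2 signal over all 6 arrays, which gave 12464 genes. Genes of the fixed lists with no probe set in the annotation given are not analysed here and are counted only.

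Knockout and normal arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment over all kept probe sets and a threshold of 0.05. Values in brackets after a log2 difference are its standard error unless stated otherwise. The 28 gene lists were fixed before the data were examined, as were the tests, the alternatives and the rule for naming genes. The lists come from general knowledge of the field, so the ureteric bud tip list may hold genes first picked in studies like this one and is not fully independent. The 26 lists with at least 5 measured members were tested with camera at an inter-gene correlation of 0.01 and again with an estimated correlation, and with the directional and mixed fry tests, each adjusted over the lists by Benjamini-Hochberg. The tip list minus the general ureteric list was tested by exact permutation of the arrays. Named genes are Ctnnb1, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups do not overlap, up to 4 passing members of each list or, where none passed, the 2 with the smallest p, and a few kidney genes fixed by name. Other members mentioned below were chosen after their values were seen.

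The fit was tested on simulated data with the real mean of each probe set and its spread as moderated by limma in the knockout against normal comparison. The noise was normal and independent between probe sets. Scatter near the floor and correlation between genes were not simulated, so recovery and false calls may differ in the real data. Of 67 probe sets changed 1.5-fold, 16.4% were recovered, of 67 changed 2-fold 50.7%, and of 66 changed 4-fold 80.3%, with 6 false calls among 27022 probe sets. The number of arrays, 3 against 3, limits the precision. Alternatives covered other scalings, other filters on dim probe sets, a pseudocount of 4.9, other variance models, array weights, a plain Welch test, the replicate number as a block, the mean of all probe sets of a gene, other thresholds and leaving out each array in turn. A reference gene table of assembly GRCm38.p6 was used for gene names and for which genes neighbour each other, and no coordinates are given because no genome build belongs to the array values.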

Results

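The series asks which genes differ in the early kidney when beta-catenin, the adhesion protein that also carries canonical Wnt signals to the nucleus, is removed from the ureteric bud, the epithelial tree that becomes the collecting ducts. There were 6 arrays, 3 from normal kidneys and 3 from Hoxb7-Cre beta-catenin conditional knockout kidneys, all at embryonic day 12.5. Their number limits the precision of every value below. Correlations of log2 signals over kept probe sets ran from 0.961 to 0.971 among normal arrays, from 0.973 to 0.977 among knockout arrays and from 0.951 to 0.974 between the groups. The ratio of 3' to 5' signal, a sign of RNA integrity, lay between 0.788 and 0.832 for Gapdh and between 1.27 and 1.42 for beta-actin on the 6 arrays. The control probe set for the 5' part of 18S ribosomal RNA was uneven, at 103, 339 and 2101 in normal replicates 1 to 3 and 5024, 1357 and 3881 in knockout replicates 1 to 3. Its log2 difference of 2.83 (SE 1.25) did not pass (limma adjusted p = 0.954 over the 64 controls).

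The targeted gene, Ctnnb1, was measured by 3 probe sets, and its signal was not lower in the knockout arrays. The brightest probe set read 5707, 6760 and 6549 in normal replicates 1 to 3 and 6777, 6779 and 6586 in knockout replicates 1 to 3. The knockout minus normal difference was 0.09 (SE 0.08) on the log2 scale, with a limma adjusted p of 0.695. The other Ctnnb1 probe sets differed by 0.16 (adjusted p = 0.601, limma) and 0.12 (adjusted p = 0.695, limma). Where these probes lie relative to exons 2 to 6 is not analysed here, and whole kidneys also hold cells outside the ureteric bud, so these values do not check the labels. One label field of the knockout samples reads as normal, against their titles, and every direction below follows the titles. Hoxb7, whose promoter drives the recombinase, lay below the filter on dim probe sets, with a highest signal of 7.6 on any array.

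In the comparison of knockout with normal kidneys, 75 genes passed the threshold, 49 higher and 26 lower in the knockout. Without normal replicate 1 there were 51 higher and 11 lower, and the count of falls also dropped when any other array was left out. The rises with the smallest p were Rpgrip1, a protein of the photoreceptor cilium, and Tmem14c, a mitochondrial membrane protein needed for heme synthesis. Rpgrip1 rose from 287 ± 43.6 to 2348 ± 62.6 (mean ± SD, n = 3 per group), a log2 difference of 3.04 (SE 0.11) with a limma adjusted p of 7.14e-06. Tmem14c rose from 97.4 ± 10.6 to 607 ± 4.78, a log2 difference of 2.64 (SE 0.12) with a limma adjusted p of 2.02e-05. A pair of genes whose products form ATP-sensitive potassium channels rose as well, Kcnj11 by 1.95 (SE 0.18) and Abcc9 by 1.87 (SE 0.24). Rgs5, a regulator of G-protein signalling typical of pericytes, rose by 1.78 (SE 0.18), and its 3 other probe sets also passed the threshold, at 1.74, 2.00 and 3.97. Rbbp9 (1.85), Cdhr1 (1.84), Pdgfd (1.72), Gm6958 (2.04) and Rmst (3.20) completed the largest rises. Rmst, a long non-coding RNA, read 12.2, 3.4 and 4 on the normal arrays, under the filter level of 14.7, so the size of its rise is poorly measured.

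The largest falls were Gm3134 (log2 difference -2.40), Ap1s3 (-2.13), Gm13306 (-2.08) and Wdfy1 (-1.90). Gm3134 read 12.7, 12.5 and 8.6 on the knockout arrays, under the filter level of 14.7, so the size of its fall and its rank are poorly measured. Ap1s3, a subunit of the AP-1 clathrin adaptor, fell from 353 ± 73.7 to 84.8 ± 33.9 (mean ± SD, n = 3 per group; limma adjusted p = 0.0233). Wdfy1, an endosomal adaptor protein, fell from 267 ± 45.8 to 74.8 ± 31.0 (n = 3 per group; limma adjusted p = 0.0183), and another of its probe sets passed too, at -1.74. Further falls were Hddc3 (-1.73), Thg1l (-1.56), Cuedc1 (-1.45), the heparan sulfate proteoglycan Sdc4 (-1.43), the aspartic protease Ctse (-1.43) and the planar cell polarity cadherin Celsr1 (-1.37). Of these 20 rises and falls, 11 genes had further kept probe sets, 17 in all. Among them 6 passed the threshold in the same direction and 4 had the opposite sign, namely those of Hddc3 (0.49), Sdc4 (1.08), Thg1l (0.12) and Pdgfd (-0.14), so for these 4 genes the change holds for the brightest probe set alone. With the mean of all their probe sets, the log2 difference was -0.62 for Hddc3, -0.18 for Sdc4, -0.72 for Thg1l, 0.79 for Pdgfd and, with further probe sets at -0.07 and -0.03, -0.51 for Cuedc1, none of which passed. The brightest probe set was chosen over all 6 arrays, so a rise in the knockout helps a probe set to be chosen. In normal kidneys the chosen probe sets of Pdgfd (mean 35.6) and Rmst (6.53) were dimmer than the other ones (40.5 and 11.3).

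**Figure D1:**
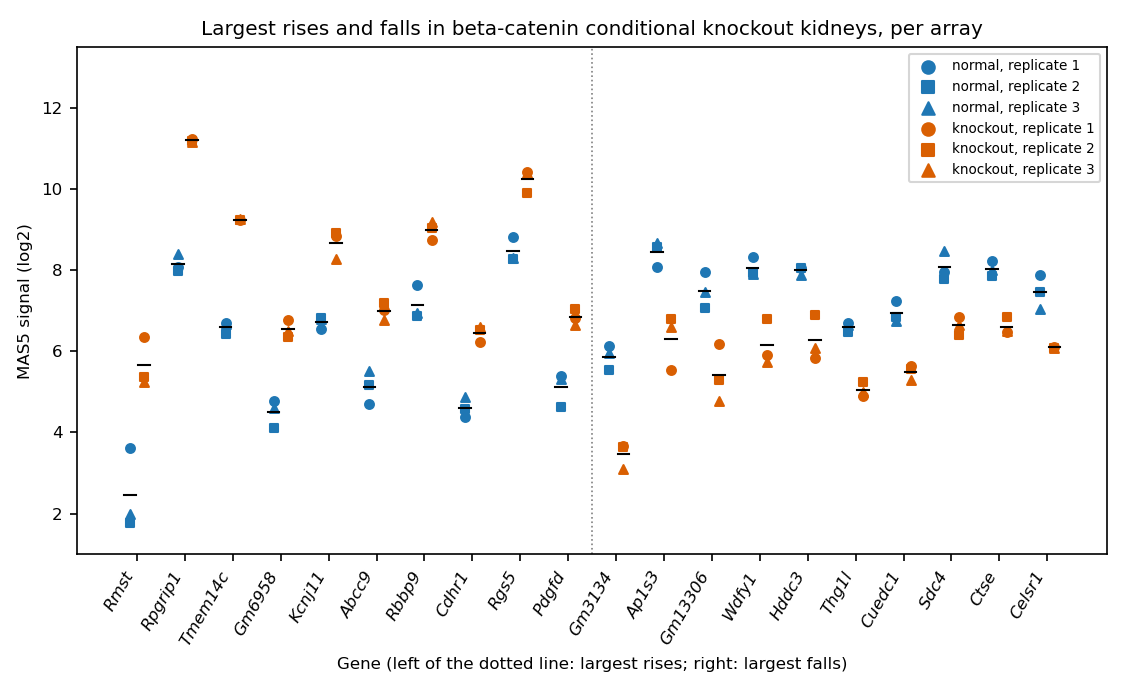
MAS5 signal on a log2 axis for the 10 largest rises (left of the dotted line) and the 10 largest falls (right), with 1 point per array, blue for normal and orange for knockout kidneys, marker shape for the replicate number and a black bar for the mean of each group. By the rule for naming these genes, the knockout arrays lie on 1 side of the normal arrays for every gene, for example Tmem14c, at 602.9, 605.6 and 612.2 in the knockout.

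By probe set, 157 passed in the limma fit with Benjamini-Hochberg adjustment, 103 higher and 54 lower, and 25 of them carry no single gene symbol. A gene counts among the 75 by its brightest probe set alone. Of the 75 genes, 45 had further kept probe sets, 68 in all. Among these 68, 12 passed the threshold in either direction and 19 had the opposite sign to the called one. With the mean of all probe sets of a gene, 65 genes passed, 41 of them among the 75. All 75 genes had knockout arrays entirely above or below the normal arrays, which passing the threshold with 3 arrays per group nearly ensures. So did 19.3% of all genes tested, where chance gives 10%. Genes are correlated and this share was not computed for other splits of the arrays, so the excess cannot be judged. The count of genes was 14 without knockout replicate 3, 19 without knockout replicate 1, 23 without knockout replicate 2, 42 without normal replicate 3, 49 without normal replicate 2 and 0 when each probe set was tested on its own variance. It was 9 without normal replicate 1 and knockout replicate 1, both high in chromaffin and neural genes, a fit chosen after seeing the data. The higher and lower genes were 36 and 13 without normal replicate 2, 30 and 12 without normal replicate 3, and 11 and 8, 14 and 9, and 9 and 5 without knockout replicates 1, 2 and 3. Without the intensity trend they were 12 and 3. Of the 20 named rises and falls, 6 (Rpgrip1, Tmem14c, Kcnj11, Rbbp9, Rgs5 and Ctse) passed with each of the 6 arrays left out in turn.

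No member of any of the 28 fixed lists passed over all genes tested, among 491 distinct genes measured by limma with Benjamini-Hochberg adjustment. Of these 491 genes 91 had an unadjusted p under 0.05, against 1459 of all 12464 genes tested. There were 23 list entries that passed when adjusted over the list alone. By camera at the preset correlation 5 of the 26 tested lists passed, 2 lower and 3 higher in the knockout. None passed with an estimated correlation or by the directional fry test, whose smallest adjusted p was 0.119. In each of these tests 1 list had an unadjusted p under 0.05. The mixed fry test, which counts changes in either direction, passed 0 lists (smallest adjusted p = 0.0585), with 7 at an unadjusted p under 0.05. These were renal vesicle (0.00225), ureteric bud tip (0.0149), basement membrane (0.0150), p53 targets (0.0202), collecting duct and urothelium (0.0323), hypoxia (0.0470) and nephron progenitors (0.0476). Of the named genes outside the 20 rises and falls, 30 had further kept probe sets, 41 in all. Among them 6 had the opposite sign, those of Btg2 (-0.02), Ccna2 (-0.17), Ccnd1 (0.11), Etv4 (0.16), Jag1 (0.35) and Lef1 (0.02), and the values below are those of the brightest probe set unless stated otherwise.

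The renal vesicle and early nephron list, genes that mark the first epithelial stages of the nephron, was lower in all 3 knockout arrays, at -0.25, -0.43 and -0.35 relative to the mean of the normal arrays. The normal arrays lay at 0.08, 0.00 and -0.08. Its mean log2 difference was -0.35 (95% interval from -0.55 to -0.14, 23 members; camera adjusted p = 1.96e-06; adjusted p = 0.553 with an estimated correlation). Of the 23 members 20 were lower, 0 passed over all genes tested and 8 passed when adjusted over the list alone, 7 lower and 1 higher. The lower ones were led by Wnt4, the signal that drives mesenchyme to form epithelium, at -0.95 (SE 0.22), the Notch target Hey1 at -0.78 (SE 0.16), Tmem100 at -0.77 (SE 0.18) and the Notch ligand Jag1 at -0.57 (SE 0.13). Sfrp2, a secreted Wnt antagonist, was the higher one, at 0.30 (SE 0.09). Over all genes tested, the limma adjusted p was 0.0963 for Hey1, 0.127 for Jag1, 0.133 for Wnt4 and 0.154 for Tmem100. Muscle genes moved with this list in part: their list stood at 1.18 and 3.02 in knockout replicates 1 and 2 but at -0.03 in knockout replicate 3, where the renal vesicle mean was -0.35. In knockout replicates 1 to 3 the macrophage list stood at 0.42, 0.87 and 0.51 and the erythroid list at 0.57, 0.18 and 0.97, above the mean of the normal arrays in all 3, as the basement membrane list lay below it. The groups overlapped for both: normal replicates 1 to 3 stood at 0.48, -0.57 and 0.09 for macrophages and at -0.27, 0.53 and -0.26 for the erythroid list.

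**Figure D2:**
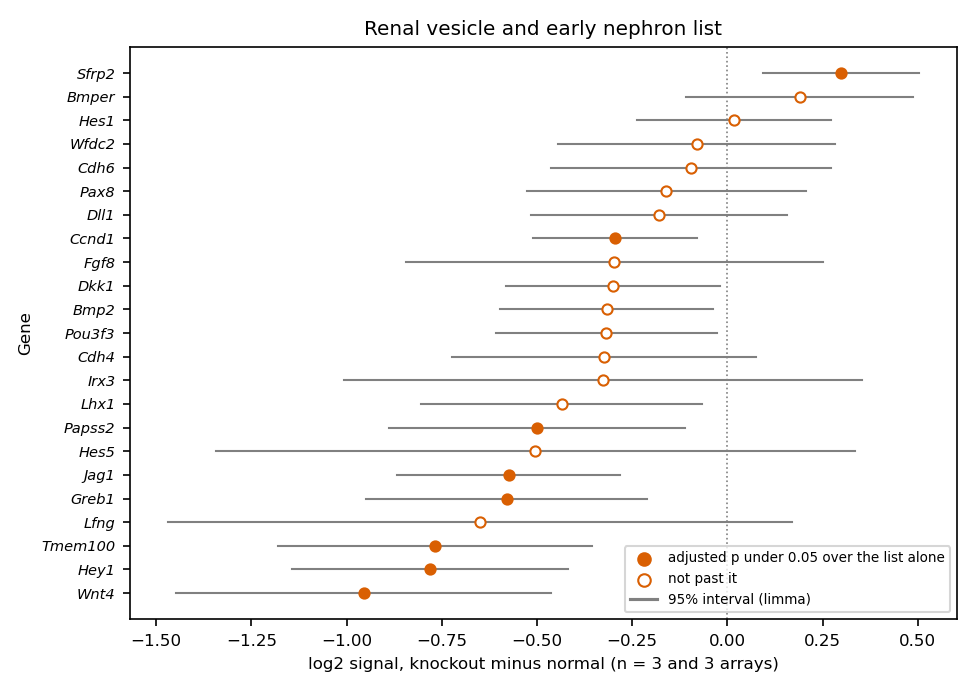
Knockout minus normal log2 signal (horizontal axis) of the 23 measured genes of the renal vesicle and early nephron list (vertical axis), from 3 arrays per group, with 95% intervals from limma as grey lines. Filled points are the 8 genes past 0.05 when adjusted over the list alone, from Wnt4 at -0.95 to Sfrp2 at 0.30.

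The basement membrane and extracellular matrix list was lower by a mean of -0.27 (95% interval from -0.55 to 0.01, 25 members; camera adjusted p = 1.75e-06; adjusted p = 0.755 with an estimated correlation). Of its members 22 were lower, 0 passed over all genes tested and 5 passed when adjusted over the list alone, all lower. They were the collagen chain Col4a2 at -0.51 (SE 0.12), the proteoglycan Agrn at -0.38 (SE 0.09), the laminin chains Lama5 at -0.69 (SE 0.19) and Lama1 at -0.60 (SE 0.17), and Frem1 at -0.28 (SE 0.09). Without normal replicate 1, the normal array with the highest mean for this list, the mean difference was -0.16. The list stood at -0.24, -0.22 and -0.36 in knockout replicates 1 to 3 and at 0.22, -0.10 and -0.12 in normal replicates 1 to 3.

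Genes of the ureteric bud itself, the tissue in which the recombinase acts, did not pass as lists. The ureteric bud tip list had a mean log2 difference of -0.09 (17 members; camera adjusted p = 0.403) and the general ureteric epithelium list also -0.09 (30 members; camera adjusted p = 0.345). Knockout replicate 2 was the lowest array for both. In knockout replicates 1 to 3 the tip list stood at 0.06, -0.32 and -0.01 and the epithelium list at 0.11, -0.26 and -0.12, relative to the mean of the normal arrays. No tip member passed over all genes tested and 2 passed when adjusted over the list alone, the transcription factor Sox9 at 0.50 (SE 0.13) and the chemokine receptor Cxcr4 at -0.55 (SE 0.15). In all, 7 of the 17 tip members had an unadjusted limma p under 0.05, against 1459 of the 12464 genes tested. Of these 7, 5 were lower, with Etv4 (-0.66) and Etv5 (-0.29) among them, and 2 were higher, Sox9 and Mmp14 (0.31). Such opposite changes cancel in part in a list mean. The tip list minus the epithelium list was 0.57 ± 0.05 in normal and 0.57 ± 0.09 in knockout arrays (log2, mean ± SD, n = 3 per group; exact two-sided permutation p = 1, where 0.1 is the smallest this design allows), and the 95% interval of the difference ran from -0.19 to 0.19. Among tip genes fixed by name, Wnt11 differed by -0.01 (SE 0.13) and the GDNF co-receptor Gfra1 by 0.02 (SE 0.13). Emx2 stood at -0.54 (SE 0.22; limma adjusted p = 0.404). Lhx1 was at -0.43 (SE 0.16; limma adjusted p = 0.380). For the GDNF receptor Ret the probe sets disagreed, the brighter at -0.05 (SE 0.21) and the dimmer at -0.73 (SE 0.23; limma adjusted p = 0.311). In the epithelium list, with 0 members past either adjustment, the smallest p belonged to Lama5 and to E-cadherin (Cdh1) at 0.32 (SE 0.15). Wnt9b differed by -0.04 (SE 0.21).

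The canonical Wnt target list had a mean log2 difference of -0.08 (95% interval from -0.35 to 0.19, 19 members; camera adjusted p = 0.345), with 0 members past either adjustment. Relative to the mean of the normal arrays, the list stood at 0.22, -0.09 and -0.13 in normal replicates 1 to 3. It stood at -0.12, -0.06 and -0.06 in knockout replicates 1 to 3, so the difference rests on normal replicate 1. The smallest p in the list belonged to Nkd1 at -0.43 (SE 0.13) and Ccnd1 at -0.30 (SE 0.09). Of the 4 members with an unadjusted limma p under 0.05, 3 were lower, these genes and Dkk1 (-0.30), and 1 was higher, Wif1 (1.42). Wif1 averaged 13.1 in normal kidneys, under the filter level of 14.7. It read 79 in knockout replicate 2 against 24.7 and 21.4 in knockout replicates 1 and 3. Its poorly measured rise lifts the list mean, and the list median was -0.09. The widely used targets Axin2 and Lef1 stood at -0.37 (SE 0.26) and -0.18 (SE 0.25). The Wnt pathway component list had a mean of -0.02 (35 members; camera adjusted p = 0.920). Beside Wnt4, the Wnt agonist Rspo3, at 0.52 (SE 0.11), passed when adjusted over the list alone, 2 genes in all, with 0 over all genes tested. Cadherins and catenins (mean -0.05, camera adjusted p = 0.649) had 0 members past either adjustment, the smallest p being that of Cdh1 and of Ctnnd2 at 0.40 (SE 0.19). The collecting duct and urothelium list had a mean of 0.39 but a median of 0.11 (17 members; camera adjusted p = 0.0848) and 0 members past either adjustment. Upk2, a urothelial plaque protein, stood at 2.36 (SE 0.60) from a mean signal of 9.83 in normal kidneys, under the filter level, and the water channel Aqp3 read 10.97 ± 8.31 in normal and 25.7 ± 5.47 in knockout kidneys (mean ± SD, n = 3 per group).

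Among the mesenchymal lists, nephron progenitors had a mean log2 difference of -0.08 (23 members; camera adjusted p = 0.440), with 0 members past over all genes tested and 2 when adjusted over the list alone, Meox1 at 0.66 (SE 0.16) and Uncx at -0.70 (SE 0.18). The progenitor factor Six2 stood at -0.49 (SE 0.23; limma adjusted p = 0.454) and Gdnf, the ligand of Ret, at -0.52 (SE 0.23; limma adjusted p = 0.444). Renal stroma had a mean of 0.09 (26 members; camera adjusted p = 0.315), with 0 members past over all genes tested and Fibin, at 0.77 (SE 0.15), the 1 gene past when adjusted over the list alone. Pdgfrb stood at -0.33 (SE 0.11) and Foxd1 at 0.16 (SE 0.10). The podocyte and proximal tubule list (mean -0.14, camera adjusted p = 0.461; Lrp2 at -0.70, Foxc2 at -0.33) and the endothelial list (mean -0.08, camera adjusted p = 0.461; Kdr at -0.40, Robo4 at -0.62) had 0 members past either adjustment.

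Of lists for signals and cell state, p53 targets and cell death had a mean log2 difference of 0.15 (14 members; camera adjusted p = 0.128), with 0 members past over all genes tested and 3 when adjusted over the list alone, all higher. These were the antiproliferative gene Btg2 at 0.93 (SE 0.20; its other probe set, of similar signal, at -0.02), Phlda3 at 0.55 (SE 0.15) and the proapoptotic gene Bcl2l11 at 0.38 (SE 0.11). Proliferation genes had a mean of -0.03 (camera adjusted p = 0.461; Plk1 at -0.39, Ccna2 at 0.21 and, by its other probe set, -0.17), and hypoxia and glycolysis genes one of -0.07 (camera adjusted p = 0.0748; Ddit4 at 0.32, Hk2 at -0.44). Means were 0.02 for immediate early and dissection stress genes (camera adjusted p = 0.835; Klf4 at 0.71 and, by its other probe set, 0.01, Atf3 at 0.59), -0.06 for the retinoic acid pathway (camera adjusted p = 0.537; Aldh1a3 at -0.69, Rarg at -0.41) and -0.06 for FGF and receptor tyrosine kinase feedback (camera adjusted p = 0.345; Fgfr1 at -0.39, Etv4 at -0.66). They were -0.02 for the BMP and TGF-beta pathway (camera adjusted p = 0.461; Bmp2 at -0.32, Bmp7 at -0.35), -0.03 for the Hedgehog pathway (camera adjusted p = 0.819; Gli1 at -0.51, Smo at -0.14) and -0.08 for Hox genes (camera adjusted p = 0.249; Hoxd13 at 1.26, Hoxb4 at -0.53). In these last 8 lists 0 members passed either adjustment.

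Markers of other tissues also differed between the arrays. The muscle list had the largest mean difference of the tested lists, 1.39 (95% interval from -0.40 to 3.18, 14 members; camera adjusted p = 1.73e-04; adjusted p = 0.799 with an estimated correlation), with 0 members past either adjustment. It stood at 3.02 in knockout replicate 2, 1.18 in knockout replicate 1 and -0.03 in knockout replicate 3. Without knockout replicate 2 the mean difference was 0.57, without knockout replicate 3 it was 2.10. The myosin light chain Myl1 read 893 in knockout replicate 2 and 77.8 in knockout replicate 1, against 14.3 in knockout replicate 3 and at most 24.3 in normal kidneys. Actc1 read 2459 in knockout replicate 2, and Myl4 read 440. The macrophage and leukocyte list was higher by a mean of 0.60 (19 members, 18 of them higher; camera adjusted p = 7.25e-07; adjusted p = 0.799 with an estimated correlation), with 0 members past either adjustment. Without normal replicate 2 it was higher by 0.31. Its smallest p belonged to the complement gene C1qb at 0.74 (SE 0.24) and to Cx3cr1 at 0.93 (SE 0.32). The erythroid list was higher by 0.58 (10 members; camera adjusted p = 0.0413; adjusted p = 0.799 with an estimated correlation), with 0 members past either adjustment and Klf1 at 0.86 (SE 0.34) and Alas2 at 1.25 (SE 0.50). The erythroid call was lost without normal replicate 1 (0.52), normal replicate 3 (0.44), knockout replicate 1 (0.58) or knockout replicate 3 (0.38).

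The list of neurons, glia and chromaffin cells had a mean difference of 0.16 (camera adjusted p = 0.426; Isl1 at 1.30, Gap43 at 0.58) and varied within both groups, at 0.94 in normal replicate 1 and 0.77 in knockout replicate 1 but -0.80 in normal replicate 2. Adrenal and gonadal genes had a mean of -0.20 (6 members; camera adjusted p = 0.441; Dppa3 at -0.84, Mc2r at -0.28). Liver and gut genes (3 measured; Afp at 1.37, Apoa2 at 0.84) and sex-linked genes (4 measured; Xist at 2.08, Kdm5d at 1.33) were too few to test as lists. The sex-linked differences rest on single normal arrays, with Xist at 15 in normal replicate 2 and Kdm5d at 2.2 in normal replicate 1. The mean Kdm5d signal was 93.9 in normal and 89.8 in knockout kidneys. In these 4 lists 0 members passed either adjustment.

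**Figure D3:**
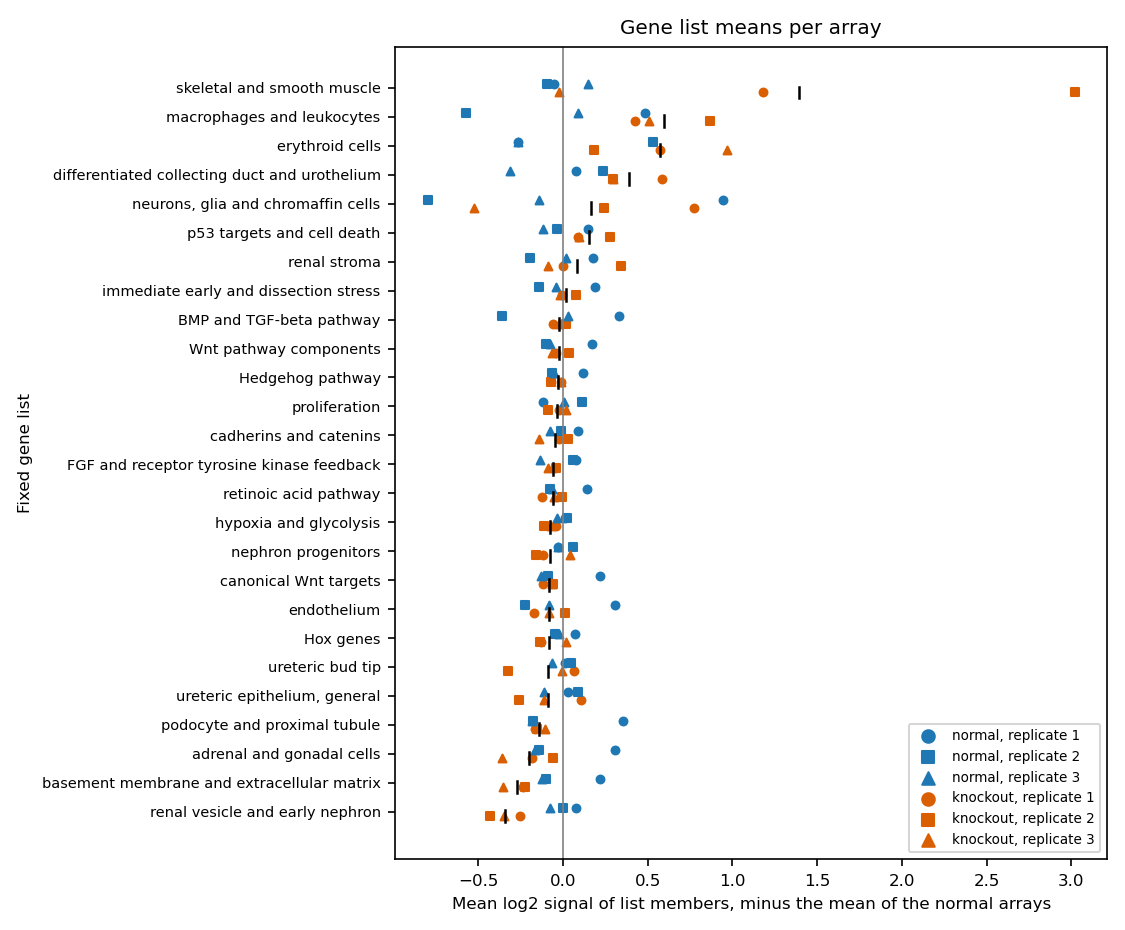
Mean log2 signal of the members of each of the 26 tested lists (vertical axis) minus the mean of the 3 normal arrays (horizontal axis), with 1 point per array, blue for normal and orange for knockout kidneys, and a black tick for the mean of the knockout arrays. The renal vesicle list is low in all 3 knockout arrays (-0.25, -0.43 and -0.35), whereas the muscle list is high in knockout replicates 2 (3.02) and 1 (1.18) alone.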

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

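The fit without normal replicate 1 and knockout replicate 1, both high in chromaffin and neural genes, was chosen after seeing the data. It called 9 genes, 29 probe sets and 10 lists, against 75, 157 and 5, and put the erythroid mean at 0.44. All other alternatives were fixed before the data were examined. Scaling each array to the same median gave 124 genes and 434 probe sets, 56 of the genes being among the 75, and the estimated prior degrees of freedom of the variance went from 4.95 to 41.8. Without the intensity trend 15 genes and 41 probe sets passed, with 2.16 prior degrees of freedom. A plain Welch test with Benjamini-Hochberg adjustment called 0 genes and 0 probe sets, with 1006 genes and 1919 probe sets at an unadjusted p under 0.05. At an adjusted p under 0.1 the limma fit called 124 genes and 253 probe sets. Leaving out 1 array gave 14 to 62 genes and 47 to 149 probe sets, with fewer samples in the fit, and an erythroid mean of 0.38 to 0.84. The erythroid call ended with cyclic loess (0.58), the filter at the 60th percentile (0.53) and no trend (0.58), and the cause was not tested. With the tip list reduced to the genes no other list holds, the tip minus epithelium difference was 0.092 (exact permutation p = 0.3) in place of 0.00. Deviations of same-numbered samples correlated at 0.08, -0.11 and -0.20, and 2 of 3 normal samples did not correlate best with their own number. With so few samples this check cannot tell whether the numbers pair them, and normal and knockout replicate 1 share the high chromaffin and neural genes. The fit with the replicate block called 43 genes and 109 probe sets. The 4 other called lists kept their direction and call in every alternative run with camera at the preset correlation. They lost the call with an estimated correlation and by fry, and the Welch alternative gives no list test. The remaining values were single named genes, uncalled lists and the higher and lower counts, including those of the fit chosen after seeing the data. Of these, 1849 kept their call status or, as counts, a similar size. Another 118 lost a call or shrank as a count, and 36 gained a call or grew. A further 14 uncalled values changed sign by at least their standard error, and smaller sign changes are among the 1849. No called value turned its direction. Signal over background limits dim genes such as Rmst, Gm3134 and Upk2.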

Other observations

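The tests of neighbouring genes, of other probe sets, of list members among called genes, of the muscle list and of the renal vesicle list were chosen after the result was seen. The count over other splits of the arrays was not, and the fits with 1 array left out or another scaling, which some of these tests read, were fixed before the data were examined. Some called genes lie close together in the genome. On one stretch of chromosome 6 Abcc9, St8sia1 and Sspn were all higher in the knockout by their brightest probe sets (1.87, 1.14 and 1.49 on the log2 scale). Further probe sets of St8sia1 stood at -0.18 and -0.33, so its rise holds for the brightest alone. On chromosome 1 the neighbours Ap1s3 and Wdfy1 were both lower (-2.13 and -1.90), while Nuf2 and Rgs5 were both higher (1.10 and 1.78). Other neighbours went opposite ways, such as Shisa4 and Ipo9 on chromosome 1 (1.47 and -0.50) and Irak1bp1 and Bckdhb on chromosome 9 (0.66 and -0.59). Of 14 pairs of successive called genes within 10 tested genes, 10 went the same way and 4 opposite ways. Probe sets of one gene also moved apart. Those of Tpbg stood at -0.96, -1.13 and 1.78, and those of Dlc1 included -0.73, -2.09 and 1.04. These genes other than Abcc9, Ap1s3, Wdfy1 and Rgs5 were chosen after their values were seen.

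For the 75 genes past the threshold, the other splits of the 6 arrays into 3 and 3 gave at most 0 genes (limma). At an unadjusted p under 0.05 the other splits gave up to 674 genes and the real one 1459. Of the 10 splits, 1 (the real one) gave as many genes past the threshold, but 10 splits are too few for a share under 0.05. Called genes had another called gene among the 10 tested genes on either side in 25 cases, against a median of 8 in 10000 random sets (p = 4e-04) and at most 16 for the top genes of the other splits, and 3 called genes (Slc25a20, Lars2 and Limd1) lay among the 100 tested genes on either side of Ctnnb1 (134 in all) where 0.808 would fall by chance (one-sided exact p = 0.0471). The exact test near Ctnnb1 treats called genes as independent of each other, although called genes clustered. Lars2 and Limd1 were themselves called neighbours, both lower (-0.90 and -0.74), while Slc25a20 was higher (0.61). The value from that test may thus be too small, and its window was chosen after the result was seen. It cannot decide whether a segment was carried along with the modified Ctnnb1 allele. Chromosome segments of different origin in the groups could give the clustering, though the labels give no strain and neighbouring genes can also share regulation. Sequence variants under the probes stay open: the median ratio of the change of other probe sets to that of the called one was 0.341 (95% interval from 0.201 to 0.530, 68 probe sets), against 0.716 (0.161 to 0.919) for genes that set knockout replicate 2 apart. An effect of beta-catenin loss through Wnt target, tip and ureteric genes cannot be told apart from none, because 0 of 66 measured members were called and such a count allows a share of up to 5.44%, above the 0.605% of other genes.

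For the higher muscle list, muscle tissue carried into single samples cannot be told apart from a change of muscle-like cells in the knockout itself. Without knockout replicate 2 the mean difference kept 41.1% of its size, but that array was left out because it stood highest for this list, so the drop supports neither. Knockout replicates 1 and 3 differed by 1.21, and the normal arrays spanned 0.25. The most abundant genes of the list in that array were Actc1 at 2459, Tnnc1 at 1016 and Myl1 at 893. None of its 14 measured members is in another fixed list, and 2 were above the median kept signal in normal kidneys. Knockout replicate 3 stood at -0.03, inside the range of the normal arrays (-0.10 to 0.15), so the rise was not shared by all knockout samples. Muscle tissue carried into single samples and a muscle change that varies between knockout kidneys stay open. The labels do not give the number of animals per vial.

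The lower renal vesicle and early nephron list was set against 3 technical explanations. Dilution by other tissue would lower other kidney lists alike. The difference of this list minus that of the nephron progenitor and general ureteric lists together was -0.26 (95% interval from -0.44 to -0.08, exact permutation p = 0.1, the smallest possible). This list was picked after it had passed as lower and the others had not passed, so a difference below 0 was nearly given. The progenitor list also mixed 13 lower and 10 higher members, such as Six2 at -0.49 and Meox1 at 0.66. The test thus cannot decide on dilution, which stays open. A single unusual array and the array scaling are argued against by a mean difference that kept at least 87.6% of its size without any 1 array and at least 95.8% under quantile, median or loess scaling. No biological explanation of the lower list was tested. The loss of beta-catenin that the design names stays open as untested, as does a difference in genetic background.

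The sex-linked genes differed most among the normal samples. Normal replicate 1 read 2660 for Xist and 5.7 for Eif2s3y, and normal replicate 2 read 15 for Xist and 215 for Eif2s3y. The other 4 arrays, normal replicate 3 and all knockout replicates, held both, with Xist from 1012 to 2392 and Eif2s3y from 68.5 to 160. The chromaffin gene Chgb read 697 in normal replicate 1 and 533 in knockout replicate 1, against 16.1 to 131 on the other arrays. The 64 control probe sets, tested with limma outside the main comparison, gave 0 past the threshold (smallest adjusted p = 0.581).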
